A study of Drosophila melanogaster with 9 samples.

How the data were processed

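RNA was sequenced from whole larvae of the third instar, the last larval stage, of the OregonR strain, a wild-type laboratory stock of Drosophila melanogaster. Per the labels' protocols, first instar larvae were moved within 4 h of hatching to food with 0, 15 or 1500 ppb perfluorooctanoic acid (PFOA), a long-lived fluorinated surfactant, which corresponds to 0, 0.03623 or 3.623 µM. Each exposure chamber held 25 larvae, and 3 chambers were used per dose. Larvae were collected 84 h after egg laying, which was 60 h after hatching. RNA was extracted with TRIzol, purified again on columns and made into libraries with a stranded kit that selects polyadenylated RNA, per the labels' protocols. The 9 libraries formed 3 groups of 3, and each library came from its own chamber, so the spread between replicates includes differences between pools of larvae. The sex of the larvae is not given in the sources used here.

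The authors deposited raw counts per gene, 1 column per library, with no normalization. Trimmomatic 0.38, STAR 2.7.3a, featureCounts 2.0.0, Subread and DESeq2 1.24.0 are named in the submitters' processing notes, without their roles or settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Reads from genes that overlap on the same or opposite strands, or from near-identical copies of a gene, could therefore have been divided between them or left uncounted in ways that cannot be checked here. The table held 17632 genes and 1 line without values, which was left out. Of the gene identifiers, 17595 were found in the reference gene table, and 409 symbols given as a dot were named from it. Gene positions and exon overlaps were taken from the Ensembl annotation of build BDGP6.54, release 115, which may differ from the one used for counting.

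Total counts per library were 10973180, 8580378 and 7881367 at 0 ppb, 10303337, 10083341 and 8147392 at 15 ppb, and 8816286, 9146599 and 10417213 at 1500 ppb. In every pair of replicates the counts differed by more than sampling noise, with a chi-square per degree of freedom of 7.69 to 28.03 over genes, so all 9 libraries were counted separately. Genes with enough counts by edgeR's filterByExpr (at least 10 counts per library at the median depth, 15 in total) were kept, which left 10692 genes.

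The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors and a robust fit, on all 9 libraries with a term for the dose only, so that the 3 groups shared 1 estimate of the spread with 6 residual degrees of freedom. The comparisons were 15 ppb against 0 ppb, 1500 ppb against 0 ppb, 1500 ppb against 15 ppb and 1 test of any difference between the doses. Genes passed at a Benjamini-Hochberg adjusted p of 0.05, two-sided. Fold changes carry a prior count of 0.125, and levels are CPM (read counts scaled to a common library size with the TMM factors), given as mean ± SD over the 3 libraries of a dose. All adjusted p-values come from edgeR unless another tool is named.

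The mapping of samples, the tests, 44 gene lists and the rule for naming genes were fixed before the data were examined. The lists held 34 pathways, complexes and gene families and 10 sets of tissue or sex markers, and each was tested with limma's camera (limma 3.58.1) with the correlation between genes estimated from the residuals, Benjamini-Hochberg adjusted over the 44 lists of a comparison. A preset correlation of 0.01 and fry were the alternatives for lists. camera asks whether a list differs from the other genes, while fry asks whether the genes of a list move on balance 1 way. Named genes were, for each dose against 0 ppb, the 10 largest folds up and down among genes that passed, whose replicates did not overlap and whose symbol is not a computed gene number or a noncoding RNA name. Added to these were the 5 smallest p-values among the same genes, up to 4 members that passed from each list or otherwise its smallest p, and a fixed panel of 16 genes. For 1500 ppb against 15 ppb the 5 largest folds in each direction were taken. Outside this rule ng2, ng3, ImpE3, CG9837, CG9920, mt:lrRNA and, at 15 ppb, roX1 were chosen after their values were seen, as were the genes said to be so in the closing section.

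The alternatives were other scalings (RLE, upper quartile, library size alone), other filters, DESeq2 1.42.0, limma-voom, a non-robust fit, a replicate block, the 6 libraries of a comparison alone, a threshold of 0.01, the 20 most abundant genes left out, and each library left out in turn. A fit with the level of the male-only transcripts roX1 and roX2 as a covariate was added after the data were seen. Comparisons that share the control libraries were set beside 50 sets of simulated counts, in which all 9 libraries were drawn from each gene's mean and fitted spread with no difference between doses, and both exposed groups were compared with the same 3 simulated controls.

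The test was checked on simulated counts at the real depths, with 200 genes changed before filtering and the shares taken over those kept. For 15 ppb against 0 ppb it recovered 10.8% of genes changed by a log2 fold of 0.5, 75.8% of those changed by 1 and 93.8% of those changed by 2, in a run of 10603 genes where 5.6% of calls were false. For 1500 ppb against 0 ppb the shares were 16.4%, 71.2% and 90.9% over 10571 genes with 6.35% false calls, and for 1500 ppb against 15 ppb they were 10.4%, 65.7% and 92.3% over 10543 genes with 8.26% false calls. Each gene was drawn independently of the others, in a run per comparison. Deviations that genes share within a real pool of larvae were not simulated, so these rates may not hold for the real libraries.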

Results

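Expression was measured in pools of whole larvae raised on food with 0, 15 or 1500 ppb PFOA, with 3 libraries per dose. Library totals ran from 7881367 to 10973180 counts, and 10692 genes were tested. On the first principal component, 0 ppb replicates 1 and 3 lay at -33.71 and -41.29, 0 ppb replicate 2 at -6.74, the 15 ppb libraries between 22.6 and 30.6 and the 1500 ppb libraries between -5.34 and 11.2. The second component held the 1500 ppb libraries between 21.3 and 29.3 and the others at or below 1.09. Male-only transcripts differed among the control pools. The mean log2 CPM of roX1 and roX2, noncoding RNAs of the male dosage compensation complex, was 5.33 in 0 ppb replicate 2, 3.81 and 3.66 in 0 ppb replicates 1 and 3, and 4.81 to 5.54 in the exposed pools. Mitochondrial large ribosomal RNA took 6.13% ± 0.308 of counts at 0 ppb, 8.08% ± 0.653 at 15 ppb and 6.59% ± 0.182 at 1500 ppb (SD, n = 3), and as a gene mt:lrRNA did not pass between 15 and 0 ppb (log2 fold change 0.32, SE 0.127, adjusted p = 0.124).

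The comparison of 15 ppb with 0 ppb asks what a low dose of PFOA does to a growing larva, in a series whose title concerns faster juvenile development and mitochondrial metabolism. Of 12 genes of the salivary glue list, most of which encode secreted proteins that fix the pupa to its surface, 8 rose, 2 fell and 2 did not pass at 15 ppb (adjusted p = 0.205 for the list with an estimated correlation). Sgs3 rose from 10.03 ± 5.77 to 523 ± 99.2 CPM (SD, n = 3 each), a log2 fold change of 5.72 (SE 0.649, adjusted p = 0.00344). Fbp1, the fat body receptor that takes larval serum proteins back up before pupation, rose from 109.8 ± 23.5 to 1258 ± 279 CPM. Of 157 nuclear-encoded mitochondrial genes in 5 lists 67 fell, among them ND-75 of complex I, from 282.3 ± 20.7 to 141.2 ± 29.2 CPM, and none of the 5 lists was called (adjusted p = 0.508 for each with an estimated correlation). The type IV collagens of basement membranes, Col4a1 and vkg, fell as well, Col4a1 from 1157 ± 106 to 568.2 ± 27.2 CPM.

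Of the 12 tested genes of the glue and salivary gland list, 8 rose, 2 fell and 2 did not pass over all genes, and 9 rose and 3 fell adjusted over the list alone, with a median log2 fold change of 4.48. The list was not called, with adjusted p = 0.205 with an estimated correlation. Eig71Ee (identifier FBgn0004592, chromosome 3L, 15654472 to 15656010), an ecdysone-induced gene of the late larval salivary gland, rose from 16.68 ± 3.29 to 514.6 ± 166 CPM, with a log2 fold change of 4.95 (SE 0.26, adjusted p = 3.17e-06). Sgs3 (FBgn0003373) lies on the same arm at 11512221 to 11513402, close to Sgs7 at 11509861 to 11510247 and Sgs8 at 11508967 to 11509394. Sgs7 rose by a log2 fold change of 4.01 and Sgs8 by 3.95. Sgs5, Sgs1, Sgs4 and Sgs5bis rose by log2 fold changes of 7.20, 6.54, 5.66 and 5.28, from control levels of 1.868, 1.565, 3.509 and 8.223 CPM. The control level of Sgs1 came mostly from 0 ppb replicate 3, with 4.285 CPM against 0.2906 and 0.1193, and without that library its log2 fold change was 9.22. The members that fell, ng2 (log2 fold change -0.86) and ng3 (-0.79), belong to the new glue genes, which are expressed in the gland earlier in larval life. Reads of the related genes Sgs7 and Sgs8, and of Sgs5 and Sgs5bis, may not have been fully told apart in counting, which was not tested. The 8 higher calls were 8 without any 1 of the 9 libraries.

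**Figure D1:**
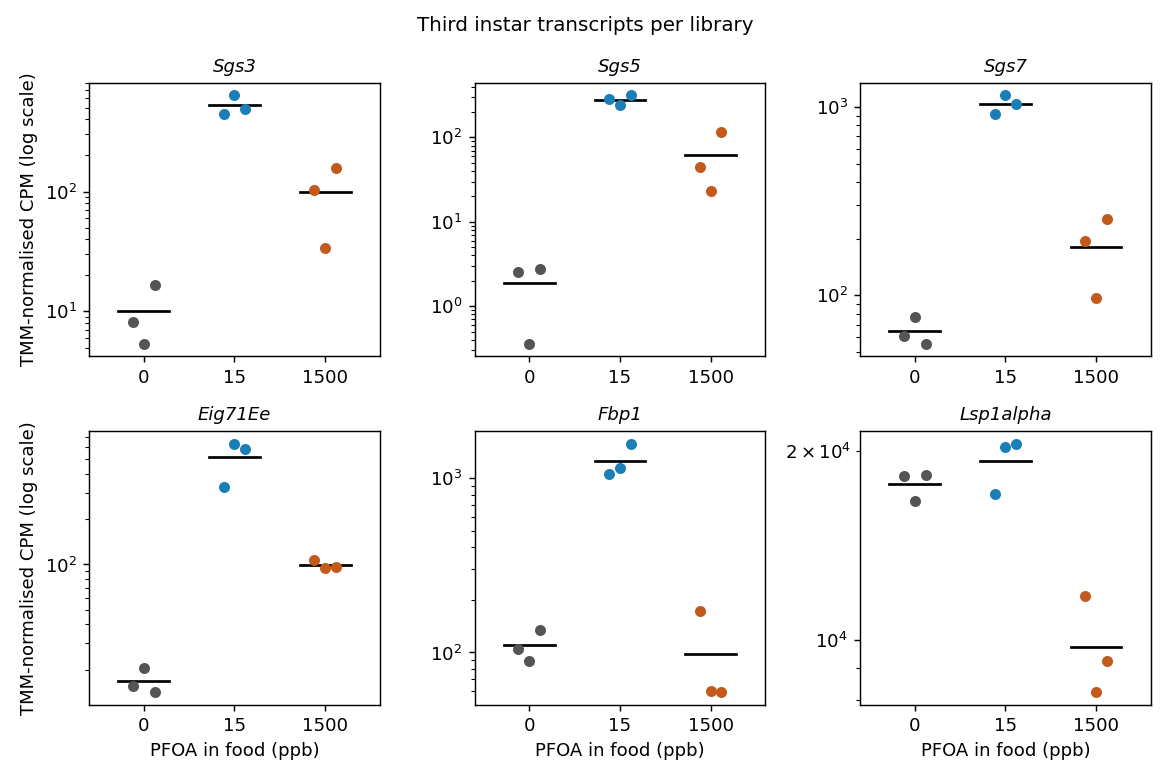
TMM-normalised CPM on a log axis of 6 genes of the glue and serum protein lists by PFOA dose in ppb, with a point per library and a line at the mean of each dose. Sgs3 averaged 10.03 CPM at 0 ppb, 523 at 15 ppb and 98.28 at 1500 ppb, and Lsp1alpha averaged 17750 CPM at 0 ppb and 9748 at 1500 ppb.

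Among 17 ecdysone response genes, which answer the steroid that triggers moulting and metamorphosis, 5 rose and 12 did not pass over all genes, and 5 rose adjusted over the list alone (adjusted p = 0.228 with an estimated correlation). The 5 include Eig71Ee, which is also in the glue list, and MsrA, which is also in the oxidative stress list, so these lists share calls. Without 0 ppb replicate 1, 3 rose. Eip74EF, an early transcription factor of the response, rose from 41.49 ± 3.29 to 70.44 ± 4.88 CPM (log2 fold change 0.76, SE 0.114, adjusted p = 0.00364). The gene br, a transcription factor that sets pupal fate, rose by 0.86 (adjusted p = 0.0102, and 0.0514 without 0 ppb replicate 1), and ImpE3 by 1.73. Eip75B had a log2 fold change of 0.06 (adjusted p = 0.846). In the list of ecdysone synthesis and turnover, 2 of 12 genes rose and 1 fell over all genes, and 3 rose and 1 fell adjusted over the list alone. The gene that fell was Cyp18a1, which inactivates ecdysone, from 19.42 ± 3.77 to 8.896 ± 1.05 CPM, while phm, an enzyme of ecdysone synthesis, had a log2 fold change of -0.44 (adjusted p = 0.252). The 6 larval serum protein genes gave 1 rise, that of Fbp1 (log2 fold change 3.52, SE 0.422, adjusted p = 0.0025), and 2 adjusted over the list alone. Lsp2, a storage protein of the list, had a log2 fold change of 0.56 (adjusted p = 0.0749). Kr-h1, which carries the juvenile hormone signal, had a log2 fold change of -0.10 (adjusted p = 0.948). It shares 78.6% of its exon length with CG45075 on the same strand and had 291 counts in all, so reads there may have been left uncounted.

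The 5 lists of nuclear-encoded mitochondrial genes held 157 genes, of which 67 fell and none rose in edgeR over all genes, with a median log2 fold change of -0.50. Of 32 complex I genes 18 fell over all genes and 25 adjusted over the list alone, of 19 genes of complexes III and IV 10 and 14, of 14 ATP synthase genes 7 and 12, of 20 citric acid cycle genes 9 and 15, and of 72 mitochondrial ribosomal protein genes 23 and 39. None of the 5 was called by camera, with adjusted p = 0.508 with an estimated correlation for each, while fry gave 0.0132 for the citric acid cycle and 0.0321 to 0.0388 for the others. SdhA, the flavoprotein of succinate dehydrogenase (FBgn0261439, chromosome 2R, 19391863 to 19395971), fell from 286.9 ± 7.4 to 166.3 ± 16.9 CPM (log2 fold change -0.79, SE 0.119, adjusted p = 0.00374). UQCR-C1 of complex III had a log2 fold change of -1.01, ND-B15 of complex I -1.31, ATPsynO of ATP synthase -0.81 and Cyt-c-p, cytochrome c, -0.99, and all passed. The 13 mRNAs encoded in the mitochondrion itself gave 0 calls in edgeR, with a median log2 fold change of 0.08. The count of 67 was 24 without 0 ppb replicate 1, 22 without 0 ppb replicate 3, 19 without 15 ppb replicate 1, 111 without 15 ppb replicate 2 and 19 without 15 ppb replicate 3. With roX level as a covariate, added after the data were seen, it was 5, with the median log2 fold change at -0.44 and the median SE at 0.187 in place of 0.151. In this comparison roX1 had a log2 fold change of 0.59 (adjusted p = 0.278) and did not pass.

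Markers of other tissues moved in the same comparison, and those of trachea and epidermis had a median log2 fold change of -0.51, close to that of the mitochondrial lists, with 6 of 22 lower. Of the midgut markers 4 of 31 fell over all genes and 1 rose and 12 fell adjusted over the list alone, with a median log2 fold change of -0.31 and adjusted p = 0.527 with an estimated correlation. Of 27 digestive protease genes, 19 of which are also midgut markers, 3 fell over all genes and 2 rose and 12 fell adjusted over the list alone, with a median of -0.37 and adjusted p = 0.556 with an estimated correlation. Among the other 12 midgut markers 2 fell over all genes, with a median of -0.222. The trypsin genes lambdaTry and betaTry had log2 fold changes of -0.79 (adjusted p = 0.00606) and -0.96 (adjusted p = 0.0157), and the call of betaTry was lost without 0 ppb replicate 1 or 0 ppb replicate 3, with up to 0.069. The 4 midgut calls were 0 without 0 ppb replicate 1 or 0 ppb replicate 3, 1 without 15 ppb replicate 1 or 15 ppb replicate 3 and 2 without 1500 ppb replicate 1, and 0 with the roX covariate. The 3 protease calls were 1 without 0 ppb replicate 1 or 0 ppb replicate 3, 7 without 15 ppb replicate 2 and 5 without 1500 ppb replicate 3, and 0 with the roX covariate. In the muscle list only Mhc passed, lower at 15 ppb, with 5795, 3881 and 5460 CPM against 9027, 7509 and 8544. Its call was lost without 0 ppb replicate 1, 0 ppb replicate 3 or 15 ppb replicate 3, with up to 0.0907. At 1500 ppb Mhc had 5711, 6938 and 5906 CPM, and no muscle marker passed against 0 ppb.

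**Figure D2:**
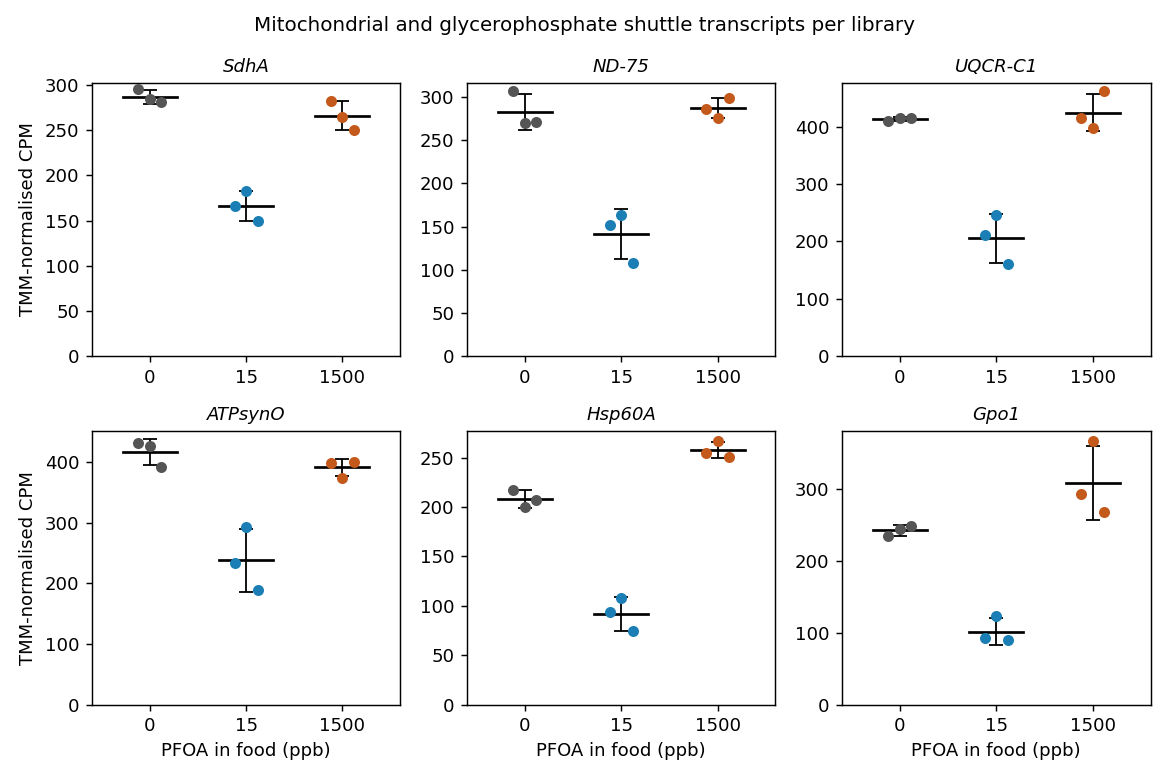
TMM-normalised CPM of 6 mitochondrial or glycerophosphate shuttle genes by PFOA dose in ppb, with a point per library, a line at the mean and bars of 1 SD. UQCR-C1 averaged 413.2 CPM at 0 ppb and 205.6 at 15 ppb, and Gpo1 averaged 242.4 and 101.6.

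In the list of mitochondrial and integrated stress genes, 1 of 19 rose and 4 fell over all genes, and 1 rose and 5 fell adjusted over the list alone (adjusted p = 0.508 with an estimated correlation). Hsp60A, the chaperonin of the mitochondrial matrix, fell from 208.1 ± 8.65 to 91.88 ± 16.9 CPM (log2 fold change -1.18, SE 0.139, adjusted p = 0.00123). Thor, the translation repressor 4E-BP, rose from 244.6 ± 64.5 to 463.1 ± 107 CPM (adjusted p = 0.0458), and leaving out 1 library at a time gave 0.0171 to 0.158, with the call lost in 6 cases. The genes crc and Ldh, the ATF4 transcription factor and lactate dehydrogenase, had log2 fold changes of 0.11 (adjusted p = 0.638) and -0.25 (adjusted p = 0.397). Of 16 genes of glycolysis and the glycerophosphate shuttle, 2 fell over all genes and 2 adjusted over the list alone. These were Gpo1 (log2 fold change -1.25, SE 0.157, adjusted p = 0.00145) and Gpdh1 (-0.65, adjusted p = 0.0154), the partners that pass cytosolic electrons to the respiratory chain. The call of Gpdh1 was lost without 0 ppb replicate 1, 0 ppb replicate 3, 15 ppb replicate 1 or 15 ppb replicate 3, with adjusted p up to 0.0693. Of 89 cytosolic ribosomal protein genes, 1 rose and 6 fell over all genes, and 1 rose and 25 fell adjusted over the list alone, with adjusted p = 0.577 with an estimated correlation. The 6 were 0 without 0 ppb replicate 1, 0 ppb replicate 3, 15 ppb replicate 1 or 15 ppb replicate 3, and 22 without 15 ppb replicate 2.

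Of 19 genes of fatty acid and triacylglycerol synthesis 4 fell over all genes and 8 adjusted over the list alone, and of 39 genes of fatty acid oxidation, lipolysis and peroxisomes 1 rose and 10 fell over all genes and 1 rose and 13 fell adjusted over the list alone. The lists had adjusted p = 0.508 and 0.527 with an estimated correlation. The 10 oxidation genes were 1 without 0 ppb replicate 1 or 0 ppb replicate 3, 2 without 15 ppb replicate 1 or 15 ppb replicate 3 and 5 without 1500 ppb replicate 1. FASN1, fatty acid synthase, fell from 2546 ± 107 to 1582 ± 178 CPM (adjusted p = 0.0462), with values of 0.0103 to 0.143 when 1 library at a time was left out and the call lost for 7 libraries. The gene whd, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose by a log2 fold change of 0.70 (SE 0.132, adjusted p = 0.0104, and 0.0514 without 0 ppb replicate 3). The lipase gene bmm had a log2 fold change of 0.37 (adjusted p = 0.133) and Hnf4, a lipid-sensing nuclear receptor, -0.15 (adjusted p = 0.38).

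Genes of the cytochrome P450, glutathione S-transferase and oxidative stress lists moved in both directions. Of 77 cytochrome P450 genes 5 rose and 2 fell, of 33 glutathione S-transferase genes 1 rose and 6 fell, and of 21 oxidative stress defence genes 1 rose and 6 fell over all genes. Adjusted over the list alone, 5 rose and 2 fell, 2 rose and 6 fell, and 2 rose and 8 fell, and the lists had adjusted p = 0.712, 0.572 and 0.556 with an estimated correlation. The 6 oxidative stress genes that fell were 3 without 0 ppb replicate 1 or 15 ppb replicate 1 and 2 without 0 ppb replicate 3 or 15 ppb replicate 3. GstD7 fell from 108.1 ± 16.3 to 52.26 ± 7.07 CPM (log2 fold change -1.05, SE 0.146, adjusted p = 0.0025). Trxr1, thioredoxin reductase, and Gclm, a subunit of the enzyme that starts glutathione synthesis, had log2 fold changes of -0.91 and -0.74 and passed, while MsrA, which repairs oxidised methionine, rose by 0.95. GstD1 fell by 0.54 on the log2 scale (adjusted p = 0.035), a call lost without any of 6 libraries, with 0.0107 to 0.115 over the 9. Cyp6a2 had a log2 fold change of -0.33 (adjusted p = 0.434). The UDP-glycosyltransferase genes named by the rule at 15 ppb, Ugt37D1, Ugt37C1, Ugt37C2 and Ugt37B1, all fell and passed.

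Structural genes of the body wall changed in both directions. Of 66 cuticle protein genes 7 rose and 9 fell over all genes, and 9 rose and 14 fell adjusted over the list alone, with adjusted p = 0.812 with an estimated correlation. The counts over all genes were 3 and 4 without 0 ppb replicate 1, 1 and 4 without 0 ppb replicate 3, 5 and 3 without 15 ppb replicate 1, 5 and 17 without 15 ppb replicate 2, and 3 and 3 without 15 ppb replicate 3. Cpr49Ac rose from 97.23 ± 2.14 to 236.9 ± 21.8 CPM, and Cpr65Ax1 fell from 74.88 ± 4.95 to 21.51 ± 11.1 CPM. Of 16 haemocyte and basement membrane genes 2 rose and 3 fell over all genes and adjusted over the list alone. These included NimC2, a phagocytosis receptor, with a log2 fold change of 2.28 (adjusted p = 0.0105), and vkg with -1.05 (adjusted p = 0.00485). Of 22 trachea and epidermis markers, 14 of which are also in the cuticle protein list, 6 fell over all genes and 8 adjusted over the list alone, with adjusted p = 0.508 with an estimated correlation. Among the other 8 markers 3 fell, with a median log2 fold change of -0.31. The 6 calls were 1 without 0 ppb replicate 1, 15 ppb replicate 1 or 15 ppb replicate 3, 2 without 0 ppb replicate 3 and 3 without 1500 ppb replicate 1, and 0 with the roX covariate. The 33 antimicrobial and immune genes, the 6 metallothioneins, the 11 digestive lipases and the 18 neuronal markers gave 0 calls in edgeR.

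Testis markers were measured beside these groups because the sex of the pools is not given in the sources used here. Of 26 testis and spermatocyte genes 4 rose over all genes and 11 adjusted over the list alone, with a median log2 fold change of 0.89 and adjusted p = 0.527 with an estimated correlation. The gene sa, a meiotic arrest gene of spermatocytes, went from 1.244 ± 0.511 to 3.513 ± 1.02 CPM (log2 fold change 1.52, SE 0.344, adjusted p = 0.0213, with up to 0.0931 and the call lost without 0 ppb replicate 1, 0 ppb replicate 3 or 15 ppb replicate 1). The 4 calls were 0 without 0 ppb replicate 1, 0 ppb replicate 3 or 15 ppb replicate 1, 14 without 0 ppb replicate 2, 2 without 15 ppb replicate 2 and 1 without 15 ppb replicate 3. In the same pools roX1 (lncRNA:roX1 in the annotation) had 118.2 ± 57.3 CPM at 0 ppb and 178 ± 50.6 at 15 ppb, and roX2 4.125 ± 3.88 and 7.399 ± 1.73, and neither passed.

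**Figure D3:**
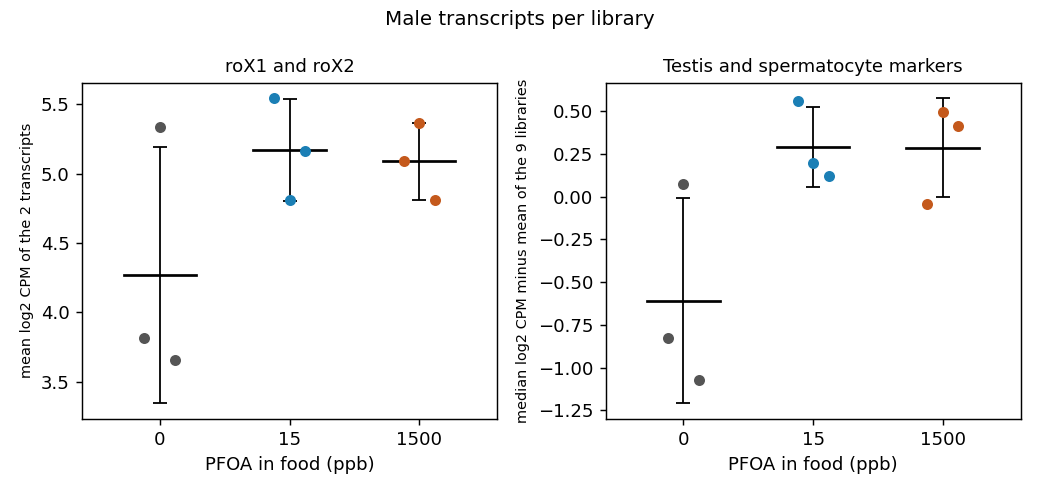
The roX transcripts and testis markers by PFOA dose in ppb, with the mean log2 CPM of roX1 and roX2 on the left and the testis markers' median log2 CPM relative to the 9 libraries on the right, a point per library, a line at the mean and bars of 1 SD. The roX mean was 4.27 at 0 ppb, 5.17 at 15 ppb and 5.09 at 1500 ppb, with 0 ppb replicate 2 at 5.33.

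In all, 920 of 10692 genes passed between 15 and 0 ppb, 389 higher and 531 lower, with 2963 genes at an unadjusted p under 0.05. The replicates did not overlap for 918 of the 920, which largely follows from selection by p. They did not overlap for 33.5% of all tested genes, where chance gives 10% on average and genes are not independent. The share of higher calls, 42.3%, was 64.6% with upper-quartile scaling and 59.3% with library size alone. Without 0 ppb replicate 1 there were 107 higher calls, 40.7% of that fit's calls. Leaving out another library gave 825 higher and 497 lower calls without 0 ppb replicate 2, 79 and 137 without 0 ppb replicate 3, 110 and 160 without 15 ppb replicate 1, and 114 and 140 without 15 ppb replicate 3. The fit with the roX covariate gave 59 higher and 54 lower. None of the 44 lists was called by camera with an estimated correlation, where 2 had an unadjusted p under 0.05, while the preset correlation gave 20 and fry 14.

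The comparison of 1500 ppb with 0 ppb asks the same of a dose 100 times as high. Eig71Ee was higher here too, at 99.28 ± 6.76 against 16.68 ± 3.29 CPM (SD, n = 3 each), a log2 fold change of 2.57 (SE 0.24, adjusted p = 0.00198). Zw (FBgn0004057, chromosome X, 19667252 to 19672353), the glucose-6-phosphate dehydrogenase that opens the pentose phosphate pathway, rose from 55.97 ± 8.51 to 97.75 ± 7.49 CPM (log2 fold change 0.80, adjusted p = 0.0446, with 0.0119 to 0.197 when 1 library was left out and the call lost for 6). Hex-C, a hexokinase, rose from 4.496 ± 1.25 to 13.46 ± 3.17 CPM, and Lsp1alpha (FBgn0002562, chromosome X, 12490291 to 12492982), a larval storage protein, fell from 17750 ± 957 to 9748 ± 1800 CPM (log2 fold change -0.86, adjusted p = 0.0482). GstD3, a glutathione S-transferase, fell from 101.7 ± 16.5 to 50.58 ± 2.83 CPM.

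The largest rise among the named genes that passed was that of the zinc transporter family gene Zip42C.2, from 0.7313 ± 0.285 to 4.978 ± 1.45 CPM (log2 fold change 2.77, adjusted p = 0.0238). eIF3f2, Nepl11, Uhg1 and Agpat2 rose by log2 fold changes of 1.97, 1.43, 0.95 and 0.94. AOX2, an aldehyde oxidase, and alpha-Est4, an esterase, had log2 fold changes of -0.71 and -0.66 and passed. The 11 other genes that passed carry computed gene numbers. Of the 12 named genes that passed, 1, Eig71Ee, passed without any 1 of the 9 libraries and under the 6 other alternatives run for named genes. The other 11 calls were each lost without 2 to 7 of the libraries, with adjusted p up to 0.223, and none was lost without 0 ppb replicate 2 or 15 ppb replicate 2.

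Of the 12 glue list genes, 1 rose over all genes and 10 adjusted over the list alone, with a median log2 fold change of 1.68 and adjusted p = 0.282 with an estimated correlation. The count over all genes was 3 without 0 ppb replicate 2, 2 without 0 ppb replicate 3, 7 without 1500 ppb replicate 2 and 2 without 1500 ppb replicate 3. Sgs3 had 98.28 ± 61.9 CPM against 10.03 ± 5.77 (log2 fold change 3.31, adjusted p = 0.0798) and Sgs5 a log2 fold change of 5.02 (adjusted p = 0.0503), and neither passed. Of 6 larval serum protein genes 1 fell over all genes and 5 adjusted over the list alone, with a median log2 fold change of -0.60 and adjusted p = 0.374 with an estimated correlation. Fbp1 and Lsp2 had log2 fold changes of -0.17 (adjusted p = 0.85) and -0.67 (adjusted p = 0.139). Of 17 ribosome biogenesis genes none rose in edgeR over all genes and 8 rose adjusted over the list alone, with a median of 0.33 and adjusted p = 0.303 with an estimated correlation.

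The 5 nuclear-encoded mitochondrial lists gave 0 calls in edgeR over all genes, with medians between -0.01 for the citric acid cycle and 0.18 for mitochondrial ribosomal proteins, the first of which changed sign with scaling. SdhA had a log2 fold change of -0.11 (adjusted p = 0.661). FASN1, Thor, Ldh and whd had 0.02, 0.28, 0.28 and -0.30, with adjusted p of 0.965, 0.576, 0.429 and 0.267. The remaining panel genes bmm, crc, Hnf4, Eip75B, Kr-h1, phm, GstD1 and Cyp6a2 did not pass either. Testis markers had a median log2 fold change of 0.89 here too, with 0 of 26 called over all genes, 14 adjusted over the list alone and 17 over all genes without 0 ppb replicate 2 (adjusted p = 0.575 with an estimated correlation). roX1 had 175.6 ± 45.6 CPM at 1500 ppb, a log2 fold change of 0.57 (adjusted p = 0.387).

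In all, 23 genes passed between 1500 and 0 ppb, 16 higher and 7 lower, with 1926 genes at an unadjusted p under 0.05, and DESeq2 gave 118 higher and 82 lower. The replicates did not overlap for the 23, which selection by p favours, or for 22.8% of all tested genes, where chance gives 10%. The share of higher calls, 69.6%, was 90.2% with upper-quartile scaling, which moved the median of all genes to 0.106, and 86.7% with library size alone. Leaving out a library gave 472 higher and 42 lower calls without 0 ppb replicate 2, 40 and 34 without 1500 ppb replicate 2, 5 and 2 without 0 ppb replicate 1, 7 and 0 without 0 ppb replicate 3, 4 and 1 without 15 ppb replicate 1, and 5 and 1 without 1500 ppb replicate 1. The lower count alone also moved, to 12 without 15 ppb replicate 2, 2 without 15 ppb replicate 3 and 12 without 1500 ppb replicate 3. None of the 44 lists was called by camera with an estimated correlation, where 5 had an unadjusted p under 0.05, while the preset correlation gave 13 and fry 3.

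The comparison of 1500 ppb with 15 ppb asks how the doses differ from each other, and roX and testis markers were near equal between them, with median log2 fold changes of -0.02 for the male dosage compensation list and 0.02 for the testis list. The cuticle protein gene TwdlP was higher at 1500 ppb, with 98.15 ± 14.6 against 11.77 ± 9.67 CPM (SD, n = 3 each, log2 fold change 3.06, adjusted p = 0.00318). Fbp1 was lower, with 97.64 ± 65.5 against 1258 ± 279 CPM (log2 fold change -3.69, SE 0.425, adjusted p = 0.00088). Of 157 nuclear-encoded mitochondrial genes 119 were called higher at 1500 ppb and none lower in edgeR, with a median log2 fold change of 0.63, and none of the 5 lists was called (adjusted p = 0.247 to 0.267 with an estimated correlation).

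Of 32 complex I genes 23 were higher over all genes and 26 adjusted over the list alone, of 19 genes of complexes III and IV 15 and 15, of 14 ATP synthase genes 11 and 12, of 20 citric acid cycle genes 12 and 15, and of 72 mitochondrial ribosomal protein genes 58 and 66. The lists had adjusted p = 0.247 with an estimated correlation, or 0.267 for ATP synthase. The 119 were 61 without 15 ppb replicate 1, 57 without 15 ppb replicate 3 and 70 without 1500 ppb replicate 1. Of 89 cytosolic ribosomal protein genes 38 were higher over all genes and 53 adjusted over the list alone (adjusted p = 0.47 with an estimated correlation), and the 38 were 18 without 15 ppb replicate 1, 14 without 15 ppb replicate 3, 57 without 15 ppb replicate 2 and 20 without 1500 ppb replicate 3. Of 16 glycolysis and shuttle genes 7 were higher over all genes and 11 adjusted over the list alone.

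Markers of other tissues moved beside the mitochondrial lists here too. Of 31 midgut markers 7 were higher and 1 lower over all genes, and 10 higher and 2 lower adjusted over the list alone, with a median log2 fold change of 0.36 and adjusted p = 0.575 with an estimated correlation. The 7 were 3 without 15 ppb replicate 1 or 1500 ppb replicate 3 and 2 without 15 ppb replicate 3 or 1500 ppb replicate 1, and the 1 lower call was kept only without 15 ppb replicate 3 or 1500 ppb replicate 1. Of 22 trachea and epidermis markers 7 were higher and 3 lower over all genes, and 8 higher and 3 lower adjusted over the list alone, with a median of 0.34 and adjusted p = 0.673 with an estimated correlation. The 7 were 4 without 15 ppb replicate 1 or 15 ppb replicate 3, and the 3 were 1 without 0 ppb replicate 1 or 15 ppb replicate 3 and 0 without 15 ppb replicate 2, 1500 ppb replicate 1 or 1500 ppb replicate 2. Among the 8 trachea and epidermis markers outside the cuticle protein list 3 were higher and 1 lower, with a median of 0.08. Among the 12 midgut markers outside the digestive protease list 1 was higher and 0 lower, with a median of 0.281.

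Of the 12 glue list genes 3 were higher and 8 lower over all genes and adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). Sgs5bis, hll, Sgs1 and Sgs8 had log2 fold changes of -3.41, -3.28, -3.08 and -2.58 and all passed, where hll lies outside the glue list. Of 6 serum protein genes 5 were lower by both counts, adjusted over the list alone included, with a median of -1.11 and adjusted p = 0.16 with an estimated correlation. These proteins come from the fat body, whose 18 markers include the 6 and gave 2 higher and 8 lower over all genes, and 2 higher and 9 lower adjusted over the list alone, with a median of -0.37 and adjusted p = 0.247 with an estimated correlation. Among the 12 fat body markers outside the serum list 2 were higher and 3 lower, with a median of -0.16. The 8 were 6 to 8 without any 1 library, and the 2 higher calls of the whole list were 0 without 15 ppb replicate 1, 15 ppb replicate 3, 1500 ppb replicate 1 or 1500 ppb replicate 2 and 1 without 0 ppb replicate 1, 0 ppb replicate 3 or 15 ppb replicate 2. Ecdysone response genes had 6 of 17 lower over all genes and 6 adjusted over the list alone, and ecdysone synthesis and turnover genes 1 higher and 5 lower of 12 over all genes and 1 higher and 7 lower adjusted over the list alone. Of 66 cuticle protein genes 20 were higher and 11 lower over all genes, and 25 higher and 15 lower adjusted over the list alone, with adjusted p = 0.857 with an estimated correlation. Zip42C.2, TwdlN and TwdlL had log2 fold changes of 3.94, 3.93 and 2.69 and passed, and TwdlO 4.04 (adjusted p = 0.0448), with up to 0.141 when 1 library was left out and the call lost for 7 libraries. The 15 ppb libraries held 1, 4 and 4 counts of Zip42C.2, 2, 5 and 0 of TwdlN, and 4, 4 and 0 of TwdlL, so the sizes of these folds are uncertain.

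In all, 1367 genes passed between 1500 and 15 ppb, 881 higher and 486 lower, with 2851 at an unadjusted p under 0.05. The replicates did not overlap for 1356 of them, which selection by p favours, and for 29.5% of all tested genes, where chance gives 10%. Leaving out a library gave 481 higher and 291 lower calls without 15 ppb replicate 1, 415 and 241 without 15 ppb replicate 3, and 522 and 295 without 1500 ppb replicate 1. None of the 44 lists was called by camera with an estimated correlation, where 6 had an unadjusted p under 0.05, while the preset correlation gave 20 and fry 16.

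In edgeR 5 genes passed at both doses against 0 ppb. Simulated counts with no difference between doses and 3 shared simulated controls gave a mean of 0.06 (0 to 1 over 50 simulations). With no changed genes a value near 0 was bound to result, so it is no measure for the overlap of real calls. Of 389 and 16 higher calls 4 were shared, where independent calls would give 0.582. Of 531 and 7 lower calls 0 were shared, where independent calls would give 0.348. Those values take no account of the shared controls. Eig71Ee, eIF3f2, CG9837 and CG9920 were higher at both, and Zw was lower at 15 ppb and higher at 1500 ppb. No gene was lower at both in edgeR, while DESeq2 gave 44 higher at both, 11 lower at both and 22 in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.578 and a Spearman rho of 0.405, where the same simulations gave a mean r of 0.51 (0.481 to 0.562). The covariance was 0.147 against 0.0363 in the simulations, and the sign was shared by 62.4% of genes against 67%. The simulations drew each library afresh from the fitted spread of each gene, so they cover sharing of controls in general but not a deviation particular to these 3 control pools. A test of any difference between the doses called 1259 genes, with 788 without 0 ppb replicate 1, 771 without 0 ppb replicate 3, 541 without 15 ppb replicate 1, 480 without 15 ppb replicate 3 and 768 without 1500 ppb replicate 1.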

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

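All tests of mitochondrial and testis patterns below, the bound and the covariate for the share of males with what ended its calls, and the splits for any difference between doses were chosen only after the result was seen, while the tests of developmental age and of roX on the calls against 0 ppb and the other splits were planned.

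Zw, glucose-6-phosphate dehydrogenase, differed between the doses because its response had opposite directions. It had 55.97 ± 8.51 CPM at 0 ppb, 29.81 ± 3.53 at 15 ppb and 97.75 ± 7.49 at 1500 ppb (SD, n = 3 each). The difference between the doses was a log2 fold change of 1.71 (SE 0.143, adjusted p = 0.000101), with -0.91 (adjusted p = 0.00444) and 0.80 (adjusted p = 0.0446) against 0 ppb. The call at 1500 ppb was lost without any of 6 libraries (0 ppb replicates 1 and 3, 15 ppb replicates 1 and 3, 1500 ppb replicates 1 and 3), with adjusted p of 0.0119 to 0.197, and had adjusted p = 0.175 with the roX covariate. Its log2 fold change was 0.70 with the covariate and 0.69 to 0.90 over the 15 alternatives, so the direction held in each while the call did not.

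The calls against 0 ppb, 920 at 15 ppb and 23 at 1500 ppb, could reflect a different share of males in the pools, since roX1 differed by log2 fold changes of 0.593 and 0.572, with roX2 and the testis markers in the same direction. A share of males as the whole cause of the higher calls at 15 ppb is argued against by 45 of 389 genes above the fold roX2 allows (log2 1.82), 8 glue genes among them. Without 0 ppb replicate 2, where roX2 itself reached 1.93 and the bound 2.52, 34 of the 389 and the 8 glue genes lay above it, as did 84 of that fit's own 825 higher calls. At 1500 ppb 5 of 16 lay above 1.64, and 4 of the 16 above 2.34 without 0 ppb replicate 2. Of each fit's own higher calls, 59 of 472 lay above the bound without 0 ppb replicate 2 and 14 of 40 without 1500 ppb replicate 2, which count against it. The others gave 2 of 5 and 6 of 7 without 0 ppb replicates 1 and 3, 3 of 4, 6 of 23 and 4 of 11 without 15 ppb replicates 1, 2 and 3, and 3 of 5 and 8 of 17 without 1500 ppb replicates 1 and 3. Those counts are small because few genes were called, so they do not favour it, and it stays open there. With the roX covariate the calls at 15 ppb went from 389 to 59 higher and from 531 to 54 lower and 108 of the 920 stayed called, with the median fold at 0.677 in place of 0.717, a ratio of 0.945, and the median SE at 0.197 in place of 0.157, and at 1500 ppb 8 of 23 stayed called with a ratio of 1.14 (SE 0.203 in place of 0.167). The wider SE (443 of 920 left at the same p limit), the changed folds (668 left) and the adjustment over all genes each ended calls, the ratio was adopted after the call counts had been seen, a first criterion on the counts would have favoured the explanation, and the slope rests largely on 0 ppb replicate 2, so male share stays a candidate explanation for part of the calls. Larvae at 15 ppb that were further in development at the same 84 h after egg laying also stay open, with glue at 4.48, serum proteins at 0.30 and the ecdysone response at 0.199. At 1500 ppb serum proteins at -0.603 beside glue at 1.68 argue against a developmental difference alone. Such a difference could itself be an effect of PFOA, which was not tested. An effect of PFOA apart from it and from male share is untested too.

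The 5 mitochondrial lists had 67 of 157 genes lower at 15 ppb and a median log2 fold change of -0.50, with adjusted p = 0.508 for each list with an estimated correlation. Trachea and epidermis markers stood at -0.51, or -0.305 over the 8 outside the cuticle protein list. Midgut markers stood at -0.31, or -0.222 over the 12 outside the digestive protease list. Different shares of these tissues were not tested. Gene length or abundance is argued against, since matched genes had a median of -0.0652 and the lowest of 10000 matched sets -0.196, and so is scaling, whose value closest to 0 was -0.41. If larvae further in development had less mitochondrial transcript, glue and mitochondrial medians would be negatively correlated within doses, and the values point the other way, with r = 0.591 over 9 libraries (exact permutation p = 0.176, Benjamini-Hochberg 0.235 over 4 relations, rho 0.85 with exact p = 0.0185, r = 0.469 without the 2 libraries farthest from the median). That r did not pass, so a difference in development cannot be told apart from another effect of PFOA at 15 ppb. Whether PFOA caused such a difference was not tested. With the roX covariate the 67 calls fell to 5. The median fold was -0.44 in place of -0.50 and the median SE 0.187 in place of 0.151. At the same p limit the new SE alone left 41, the new folds alone 48, and all together 26. The 67 were 24 and 22 without 0 ppb replicates 1 and 3, the controls with low roX. They were 61 without 0 ppb replicate 2, the control with high roX. The count also fell without 15 ppb replicate 1 or 15 ppb replicate 3. The median log2 fold change was -0.514, -0.491 and -0.507 without 0 ppb replicates 1, 3 and 2. Leaving out a control, of low or high roX, therefore changed the calls but hardly the median fold. Mean roX level was 5.17 at 15 ppb, 5.09 at 1500 ppb and 4.27 at 0 ppb. The mitochondrial median log2 CPM relative to the 9 libraries averaged -0.379 (SD 0.236), 0.251 (SD 0.0568) and 0.14 (SD 0.0151) at these doses. It was 0.133 in 0 ppb replicate 2, and 0.131 and 0.158 in 0 ppb replicates 1 and 3. These values argue against male share as the whole cause of the fall. Within doses roX level and mitochondrial median had r = -0.375 (exact permutation p = 0.0787, Benjamini-Hochberg 0.157 over 4 relations), which did not pass. The rho was -0.383 with exact p = 0.227, and r was -0.64 without the 2 libraries farthest from the median. Male share stays a candidate explanation for part of the fall.

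Testis markers had a median log2 fold change of 0.89 at both doses, with 4 of 26 called higher at 15 ppb and 0 in edgeR at 1500 ppb over all genes, 11 and 14 adjusted over the list alone, and adjusted p = 0.527 and 0.575 with an estimated correlation. A larger share of males in the exposed pools is a candidate explanation, with a within-dose correlation of roX level and testis median over 9 libraries of r = 0.864 (exact permutation p = 0.0509, Benjamini-Hochberg 0.157 over 4 relations, rho 0.783 with exact p = 0.0602, r = 0.557 without the 2 libraries farthest from the median). After the within-dose slope on roX, 0.365 of 0.9 was left at 15 ppb and 0.411 of 0.896 at 1500 ppb. A change of the testis with developmental stage or PFOA cannot be told apart from it, as the sex of the larvae is not given in the sources used here and 3 pools per dose are few.

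Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05, and 1 of them, the real one, gave as many calls in each comparison. The real split gave 920 and the highest other 0 for 15 against 0 ppb, 23 and 0 for 1500 against 0 ppb, and 1367 and 308 for 1500 against 15 ppb. For any difference between doses 1 of 100 splits, the real one with 1259, gave as many and the highest other gave 625, so chance assignment is excluded at 0.05.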

How the results depend on the processing

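The fit with the roX covariate was chosen only after the data were seen, and the other alternatives were planned. No named gene that passed reversed direction. Of the named genes that passed, 35 of 117 at 15 against 0 ppb, 1 of 12 at 1500 against 0 ppb and 8 of 10 at 1500 against 15 ppb passed under all 15 alternatives that recomputed them. RLE scaling, a non-robust fit, limma-voom and leaving out the 20 most abundant genes kept each count of called genes they recomputed within 1.5 times. At these depths with 3 libraries per dose, 10.8% of simulated genes changed by a log2 fold of 0.5 were recovered at 15 ppb, and how much of this is due to depth was not tested.

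For 15 against 0 ppb, the 389 higher calls became 59 with the roX covariate and 63 at an adjusted p of 0.01, and ranged from 79 to 825 without 1 library. The 531 lower calls became 299 with upper-quartile scaling, 804 in DESeq2, 54 with the roX covariate and 103 at 0.01, and ranged from 137 to 722. For 1500 against 0 ppb, the 16 higher calls became 46 with upper-quartile scaling, 39 with library size alone, 35 with no filter, 26 with the strict filter, 118 in DESeq2 and 1 at 0.01, and ranged from 4 to 472. The 7 lower calls became 19 with no filter, 82 in DESeq2, 2 with only the 6 samples, 0 with the roX covariate and 0 at 0.01, and ranged from 0 to 42. For 1500 against 15 ppb, the 881 higher calls became 372 at 0.01 and ranged from 415 to 1109, and the 486 lower calls became 312 with only the 6 samples and 181 at 0.01, and ranged from 241 to 546. Any difference gave 380 at 0.01 in place of 1259 and ranged from 480 to 1735. The overlap of higher calls, 4, became 1 at 0.01 and 44 in DESeq2, that of lower calls, 0, became 11 in DESeq2, and the opposite calls, 1, became 0 at 0.01 and 22 in DESeq2. The correlation of fold changes, 0.578, became 0.403 among genes of at least 5 CPM in 3 samples. Lists called, 0 in each comparison, became 20, 13 and 20 with the preset correlation and 14, 3 and 16 with fry, and 0 to 2 without 1 library for 1500 against 15 ppb. A stricter threshold lowers counts by construction. Of the 920 calls at 15 against 0 ppb, the covariate's SE alone left 443, its folds alone 668 and its degrees of freedom alone 914 at the same p limit, all together left 348, and with its own adjustment 108 stayed. For the other changes the cause was not tested.

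The replicate numbers did not pair the libraries, since 3 of 9 correlations of deviations between same-numbered libraries were over 0.1 (-0.367 to 0.235). With a replicate block, 181 higher and 231 lower genes were called at 15 against 0 ppb in place of 389 and 531, 11 and 5 at 1500 against 0 ppb, 603 and 336 at 1500 against 15 ppb, and 683 for any difference.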

Other observations

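The genes below were chosen only after their values were seen, and no test was planned for either group.

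The pentose phosphate pathway, which makes NADPH and ribose from glucose, had 7 of 8 genes looked up higher at 1500 ppb than at 15 ppb. Pgd, the NADPH-making enzyme that follows Zw, had 123.2 ± 30.1 CPM at 15 ppb and 324.3 ± 57.2 at 1500 ppb (SD, n = 3 each, log2 fold change 1.40, adjusted p = 0.000703). Taldo, CG8036, Rpi and Pgls had log2 fold changes of 1.38, 1.31, 1.08 and 1.07, Rpe 0.43 (adjusted p = 0.0311), and all passed, while CG5103, at 3.08 and 2.31 CPM, had -0.40 (adjusted p = 0.634). Against 0 ppb, Zw and Taldo were lower at 15 ppb (log2 fold changes -0.91 and -0.65, adjusted p = 0.00444 and 0.034). Zw and CG8036 were higher at 1500 ppb (0.80 and 0.82, adjusted p = 0.0446 for each). The call of Zw at 1500 ppb was lost without any of 6 libraries, and those of Taldo and CG8036 were not followed with libraries left out. Pgd, Rpi and Taldo at 1500 ppb had adjusted p of 0.0715, 0.0503 and 0.0944 and did not pass.

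Tweedle genes encode cuticle proteins that shape the body wall. Of 9 tested, 7 were higher and 2 did not pass at 1500 against 15 ppb, among them Twdlalpha with 6.444 ± 2.38 and 23.36 ± 1.79 CPM (log2 fold change 1.85, adjusted p = 0.000346), TwdlG (0.95) and Twdlbeta (0.86). TwdlX and TwdlU had log2 fold changes of 0.33 (adjusted p = 0.253) and -0.54 (adjusted p = 0.336). Control levels of TwdlP and TwdlO were 37.56 ± 7.54 and 20.69 ± 4.41 CPM, and at 1500 ppb they were 98.15 ± 14.6 and 179.3 ± 19.9 CPM, with adjusted p against 0 ppb of 0.165 and 0.193. Their log2 fold changes were 1.39 and 3.11, and the replicates of these doses did not overlap. The shared estimate of the spread includes the 15 ppb libraries, where TwdlO had 0.28, 28.9 and 3.62 CPM. Not passing is therefore no sign of equal levels. Twdlalpha was lower at 15 ppb than at 0 ppb (log2 fold change -0.95, adjusted p = 0.0183) and had 0.90 at 1500 ppb (adjusted p = 0.075). No other Tweedle gene tested passed against 0 ppb at either dose.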
